A study of Mus musculus with 108 samples.

How the data were processed

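The series holds RNA sequencing of 15 mouse hippocampal tissue libraries, 3 at each of 5 postnatal ages, and of 93 single neurons of 5 types from postnatal weeks 3 to 4. Cell types are those of the labels. Per the labels, tissue and subiculum cells were prepared with version 4 and CA1 cells with version 3 of a SMARTer cDNA kit, all followed by Nextera tagmentation. The submitters' processing notes name FastQC, cutadapt, Trim Galore, STAR and HTSeq, and the builds mm10 and hg19, without versions, order or roles. The deposited values are counts of reads per gene symbol, not normalised. The table has 23337 genes and 92 ERCC spike-in sequences, and all 108 per-sample files were identical to its columns. No gene symbol was duplicated, no column lacked a label, and no pair of libraries was identical. Spike-ins were left out of all totals and used only to describe batches. Coordinates are those of the GENCODE M21 annotation on GRCm38 (mm10). Whether libraries kept the strand is not stated, so reads of antisense partners and near-identical paralogs cannot be separated, and such genes are not interpreted.

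Gene reads ranged from 2341677 to 13262818 per tissue library and from 30025 to 11694081 per cell. Summed over a type there were 66313259 reads for CCK, 30502443 for PV, 31546502 for CA1 pyramidal, 21818186 for burst and 16519117 for regular cells. A type without a read of a gene was assigned 3 reads as an upper limit, which equals 0.0452, 0.0984, 0.0951, 0.137 and 0.182 CPM in the same order, and 0.0783 CPM for all subiculum cells. The limit over the 3 tissue libraries of an age was 0.127 CPM at P0 and 0.161 CPM at P7. A fold against a group at 0 reads is a lower bound from that limit. With 1 to 3 reads the ratio of pooled CPM is given with its exact 95% interval.

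Tissue was analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed by filterByExpr, leaving 14737 of the 19485 genes with a read, and libraries were scaled by TMM. A robust quasi-likelihood model was fitted to all 15 libraries with a term per age (common biological coefficient of variation 0.119). P28 was compared with P0, each age with the one before, and all ages together by an F test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors (SE) of log2 fold changes are the log2 fold change divided by the square root of F. CPM values of tissue are TMM-normalised means of 3 replicates. Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and adjusted over 20 lists. Each was repeated with an estimated correlation and with fry. Counts per list use p values adjusted over all genes, with counts adjusted over the list alone where these differ or are asked for. P21 was also compared with the mean of P14 and P28, a contrast chosen after the data were seen.

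The labels name no animal behind a cell, so each type was treated as 1 sample without a test. Counts were summed over the cells of a type as CPM, and the ratio of types was given an exact binomial (Clopper-Pearson) 95% interval from the split of reads. Shares of cells with a read have exact binomial intervals or were taken after each cell was thinned to 200000 reads, a depth that 1 PV, 2 CA1 pyramidal and 1 regular cell did not reach. For a list, the median log2 ratio over members of at least 10 CPM in either type is given with its percentile among 10000 random lists matched on expression in 20 bins. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

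Lists, comparisons, tests and the rule for naming genes were fixed before the data were examined. The 26 lists cover immature neurons, proliferation, myelin, oligodendrocyte precursors, astrocytes, microglia, endothelial cells and pericytes, erythrocytes, choroid plexus, glutamate receptors, GABA receptors, potassium channels, sodium, HCN and calcium channels, synaptic adhesion, cadherins and protocadherins, vesicle release, immediate early genes, heat shock, GABAergic and glutamatergic neurons, and, for cells, PV, CCK and somatostatin (SST) interneurons, CA1 pyramidal, subiculum pyramidal, and dentate and CA3 cells. The naming rule took 26 fixed genes. In tissue it added the 10 largest changes each way between P0 and P28 and the 5 largest for each step, among called genes with at least 20 CPM in the higher age and replicates that did not overlap. From each list it took the 2 largest and 2 smallest ratios. In cells it took up to 10 genes each way with at least 20 CPM, a read in at least 60% of thinned cells and at least 40 points more cells than the other type, and an equal-weight fold of at least 2. Where fewer than 5 qualified, the 5 with the largest equal-weight ratio were taken. Some genes of the rule are withheld and not named.

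Alternatives were RLE scaling, DESeq2 1.42.0, no filter, thinning to the smallest library, a replicate block, the 6 libraries of a contrast alone and each library left out in turn. For cells they were equal weight per cell, TMM scaling, a minimum of 1 CPM, and leaving out cells under the thinning depth, or for single genes the highest cell. Cells with or without spike-ins, cells under 1000 detected genes left out, the P21 libraries left out and the estimated correlation for the 4 steps were added after the data were seen. The tissue fit was tested on simulated data of 14570 genes, where it called 56% of genes with a log2 change of 1 and 100% of those with 2, and 6 unchanged genes. The simulated dispersion, the square of the biological coefficient of variation, was set to 0.05. That is larger than in the data (common coefficient 0.119), so these shares do not give the power of the real fit. The list medians of cells were tested on 100 simulated lists of 40 genes raised by 1, whose medians averaged 1.00 (0.62 to 1.33), all at or above the 97.5 percentile, and of 200 genes (0.85 to 1.12). A first trial with a single draw of 40 genes was replaced by these repeated draws. Of 100 unchanged lists, 4 of 40 genes and 2 of 200 genes fell outside the central range. These simulations drew the summed counts of each gene independently, at the depths of burst and regular cells. They held no variation between cells and no genes that vary together within a cell. Their shares therefore do not give the error of the percentiles in the data.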

Results

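RNA was sequenced from 15 pieces of mouse hippocampal tissue and from 93 single hippocampal neurons that had been recorded electrically before collection. The tissue covered postnatal days P0, P7, P14, P21 and P28, with 3 independent replicates per age. The neurons came from postnatal weeks 3 to 4 and were labelled by cell type and, apart from the CA1 pyramidal cells, by firing. There were 19 regular-spiking cholecystokinin (CCK) interneurons, 14 fast-spiking parvalbumin (PV) interneurons and 25 pyramidal cells of CA1, and 21 burst-firing and 14 regular-firing pyramidal cells of the subiculum, the output region of the hippocampus. Tissue libraries held 2341677 to 13262818 reads assigned to genes. Median depth per cell was 2611555 reads in CCK cells, 1114365.5 in PV cells, 1171579 in CA1 pyramidal cells, 909090 in burst cells and 1204765.5 in regular cells. Single cells ranged from 30025 to 11694081 reads. At least 1 read was found for 20371 of the 23337 genes in the table.

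The 5 ages of tissue show how the hippocampal transcriptome matures after birth. Among the 14737 genes with enough reads to test, 11266 differed between ages. Across genes, log expression correlated at 0.869 between P0 and P28 and at 0.977 between P14 and P28 as means over pairs of libraries, and pairs of replicates of one age at 0.973 to 0.989. The first principal component held 63.2% of the variance. Mean normalised CPM (reads per 1e+06 gene reads after TMM scaling) of Dcx, a microtubule protein of newborn and migrating neurons (mm10 chromosome X, 143855842 to 143933311), were 1109 at P0, 39.5 at P14 and 19.7 at P28. Mbp, the gene of myelin basic protein, had means of 40.1, 4917 and 4632 CPM at the same ages.

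**Figure D1:**
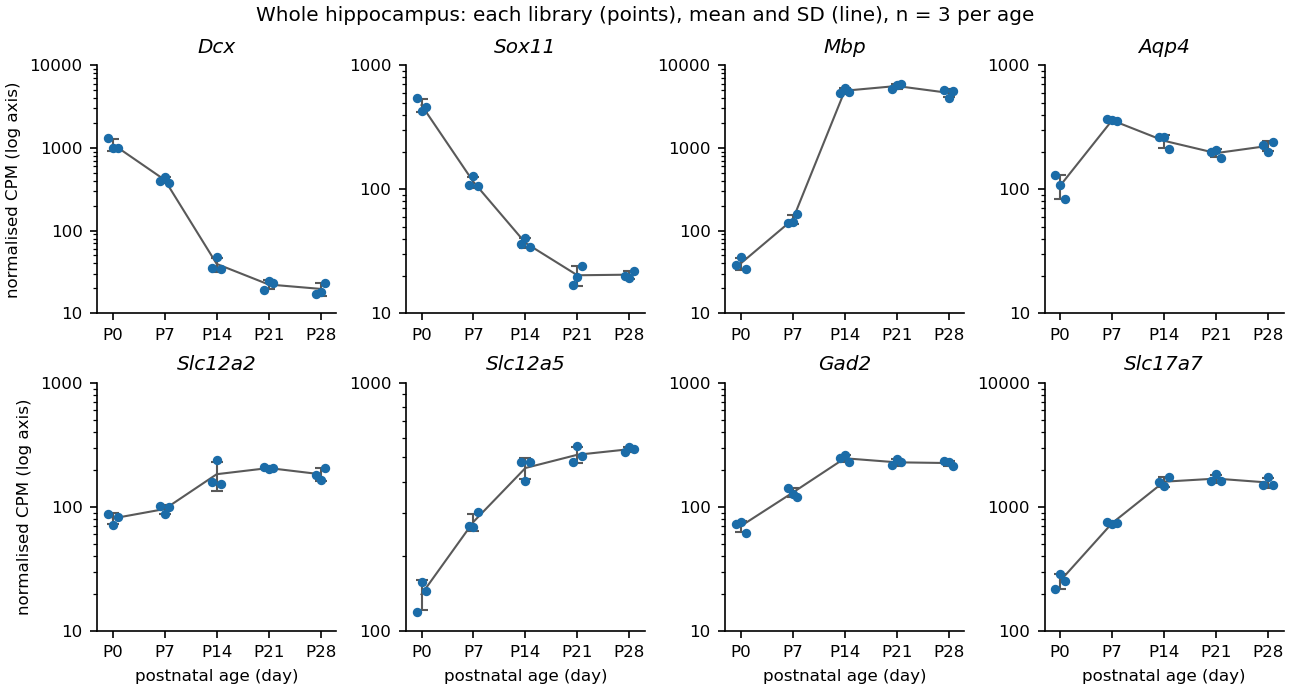
Normalised CPM (log axis) of 8 genes in the 15 tissue libraries against postnatal age in days, with a point per library and a line with bars at the mean and SD of the 3 replicates. Mean Dcx lies at 1109 CPM at P0 and 19.7 CPM at P28, while mean Mbp lies at 40.1 and 4632 CPM.

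Between P0 and P28 the hippocampus gained myelin transcripts and lost transcripts of newborn and dividing cells. All 20 myelin genes rose, with a median log2 fold change of 5.83 (camera adjusted p = 1.25e-61; adjusted p = 0.00507 with an estimated correlation). Mbp (chromosome 18, 82475146 to 82585637) went from 40.1 ± 7.00 to 4632 ± 523 CPM (SD, n = 3; log2 fold change 6.84, SE 0.15, adjusted p = 1.6e-17). Mag and Mal, membrane proteins of myelin, rose by 8.16 and 8.01. Mobp, another myelin protein, had 1 read at P0 and 454 ± 63.4 CPM at P28, a 10333-fold ratio of pooled CPM (counting interval 1854 to 4.08e+05). Nkx6-2, a transcription factor of oligodendrocytes, had no read at P0 and 23.2 CPM at P28, at least 176-fold higher.

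All 20 immature-neuron genes fell (median −2.45, adjusted p = 4.33e-35; adjusted p = 1.55e-04 with an estimated correlation), as did all 24 proliferation genes (median −3.11, adjusted p = 4.34e-14; adjusted p = 0.0102 with an estimated correlation). Dcx fell by 5.80 on the log2 scale (SE 0.17, adjusted p = 5.91e-16) and Sox11, a transcription factor of young neurons, by 4.53. St8sia2, which adds polysialic acid to the adhesion protein NCAM, dropped from 343 ± 23.5 to 3.64 ± 0.512 CPM (−6.55, SE 0.16, adjusted p = 1.25e-16). Other large decreases were those of Tnc, an extracellular matrix protein (−6.06), Avpr1a, a vasopressin receptor (−7.51), Cd24a (−5.37) and Gpc2, a glypican of young axons (−5.20). Top2a, a topoisomerase of dividing cells, fell by 4.51.

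Gad1, Gad2, Slc12a5 and Slc12a2 rose between P0 and P28, while the GABAergic-neuron list was not called. Tissue values do not tell which cell types carry these rises. Most CA1 pyramidal cells had no read of Slc12a2, but most subiculum pyramidal cells held reads of it. The CA1 pyramidal cells also had fewer detected genes per cell. Slc12a5, which encodes the chloride exporter KCC2 (chromosome 2, 164960802 to 164999731), went up by 1.93 (SE 0.10, adjusted p = 4.29e-12) and Slc12a2, the chloride importer NKCC1 (chromosome 18, 57878678 to 57946821), by 1.20 (SE 0.14, adjusted p = 3.16e-07). Gad1 and Gad2, the enzymes that make GABA, rose by 1.41 and 1.70, and the neuropeptide genes Sst, Npy and Cck by 1.65, 0.95 and 1.17. Pvalb, a calcium buffer of fast-spiking interneurons (chromosome 15, 78191114 to 78206400), had 2 reads at P0 and 15.0 CPM at P28, a ratio of 174 (counting interval 47.8 to 1438). Cnr1, the cannabinoid receptor (chromosome 4, 33924593 to 33948831), fell by 0.63 (adjusted p = 3.47e-06). Of the 14 GABA receptor genes 7 rose and 1 fell (median 0.46, adjusted p = 0.0216; adjusted p = 0.343 with an estimated correlation). Gabrd, a subunit of extrasynaptic receptors, rose by 2.99. The 1 gene that fell was Gabra2 (−0.31, adjusted p = 0.0208), a call that ended without P0 replicate 1 (−0.21, adjusted p = 0.108) and without P28 replicate 3 (−0.27, adjusted p = 0.0772). Of the GABAergic-neuron genes 4 rose and 9 fell (median −0.75, adjusted p = 0.384), among the latter the developmental regulators Dlx2 (−2.09) and Lhx6 (−1.72).

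Genes of ion channels and vesicle release rose more often than they fell. Slc17a7, the vesicular glutamate transporter of most hippocampal pyramidal cells, rose by 2.63 (SE 0.10, adjusted p = 5.27e-14) and Camk2a, a kinase of the postsynaptic density, by 3.27. Of the 25 glutamate receptor genes 13 rose and 2 fell (median 0.31, adjusted p = 0.064). The NMDA receptor subunit Grin2a went from 6.10 to 20.9 CPM (1.87, SE 0.20, adjusted p = 9.1e-08) and Grin2c rose by 4.13, while Grin3a fell by 1.74. Grin2b, the subunit that dominates early NMDA receptors, was at 165 CPM at P0 and was not called at P28 (0.31, SE 0.14, adjusted p = 0.0524). It was called with the 6 libraries of both ages alone (adjusted p = 0.0103), with thinned libraries (adjusted p = 0.0483), with a replicate block (adjusted p = 0.0221) and without P28 replicate 1 (0.40, adjusted p = 0.0234), and its adjusted p reached 0.21 in the other alternatives. Among 43 potassium channel genes 33 rose and 2 fell (median 1.28, adjusted p = 5.24e-12; adjusted p = 0.02 with an estimated correlation), led by Kcnj4 (3.78) and Kcnab2 (3.67). Of the 27 sodium, HCN and calcium channel genes 18 rose and 5 fell (median 0.73, adjusted p = 2.32e-04; adjusted p = 0.0743 with an estimated correlation). The sodium channel subunits Scn4b and Scn2b rose by 4.86 and 3.86, and the pacemaker channels Hcn4 and Hcn3 fell by 3.33 and 1.77. Of the 43 vesicle release genes 30 rose and 7 fell (median 1.21, adjusted p = 2.15e-07; adjusted p = 0.029 with an estimated correlation), with Vamp1 at 3.97 and Syt4 at −2.09.

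Cell adhesion molecules moved in both directions. Of 78 synaptic adhesion genes 27 rose, 26 fell and 25 were not called. The median log2 change was 0.07 and the mean 0.04, while camera gave the direction as down (adjusted p = 0.713). Cntnap1, a contactin partner at the node of Ranvier (chromosome 11, 101170523 to 101190724), rose by 5.53 and Chl1 and Cntn2, adhesion proteins of growing axons, fell by 1.89 and 1.55. Of genes for presynaptic neurexins, Nrxn3 rose by 1.05 (SE 0.08, adjusted p = 1.58e-09) and Nrxn2 fell by 0.63 (SE 0.16, adjusted p = 0.00232). Of their postsynaptic partners, the neuroligin Nlgn2 rose by 0.74 (SE 0.18, adjusted p = 0.00144), and Nlgn1 (0.04, adjusted p = 0.755) and Nlgn3 (0.18, adjusted p = 0.0894) were not called. Of 30 cadherins and protocadherins 8 rose and 13 fell (median −0.31, adjusted p = 0.0851), with Fat4 at −2.39 and Cdh22 going from 15.8 to 45.3 CPM.

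Glial genes accompanied these changes. Of 18 astrocyte genes 15 rose and 1 fell (median 1.33, adjusted p = 2.27e-12; adjusted p = 0.029 with an estimated correlation). Gfap, the astrocyte filament, rose by 1.33, Aqp4, a water channel, by 1.09, and the gap junction gene Gjb6 by 4.48. Of 16 microglia genes 15 rose and 1 fell (median 1.31, adjusted p = 5.82e-05; adjusted p = 0.102 with an estimated correlation), including Tmem119 (2.94). Of 10 oligodendrocyte precursor genes 6 rose and 1 fell (median 0.64, adjusted p = 0.0329; adjusted p = 0.192 with an estimated correlation). The erythrocyte list rose (median 3.69, adjusted p = 0.00351; adjusted p = 0.182 with an estimated correlation), but is not interpreted because 3 of its 4 tested genes are globin paralogs. Of 19 immediate early genes, which report recent neuronal activity, 11 rose and 3 fell (median 0.84, adjusted p = 0.0338; adjusted p = 0.343 with an estimated correlation). Arc went from 6.59 to 108.5 CPM. Endothelial and pericyte genes (6 rose, 1 fell, median 0.26, adjusted p = 0.123), heat shock genes (5 and 2, median 0.14, adjusted p = 0.897) and choroid plexus genes (7 and 0, median 4.32, adjusted p = 0.206) were not called as lists. Between the P28 libraries the choroid plexus gene Ttr differed 19.7-fold. For glutamatergic-neuron genes (5 and 7, adjusted p = 0.617) the median was −0.47, the mean 0.23 and the camera direction up.

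In all, 4846 genes rose and 4619 fell. Replicates of the ages did not overlap for 10111 of the 14737 genes (68.6%, against 10% by chance), among them 9091 of the 9465 calls. Adjusted over the list alone, the counts were 34 rising potassium channel genes, 31 rising vesicle release genes and 4 falling immediate early genes, and those of the other lists were unchanged.

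**Figure D2:**
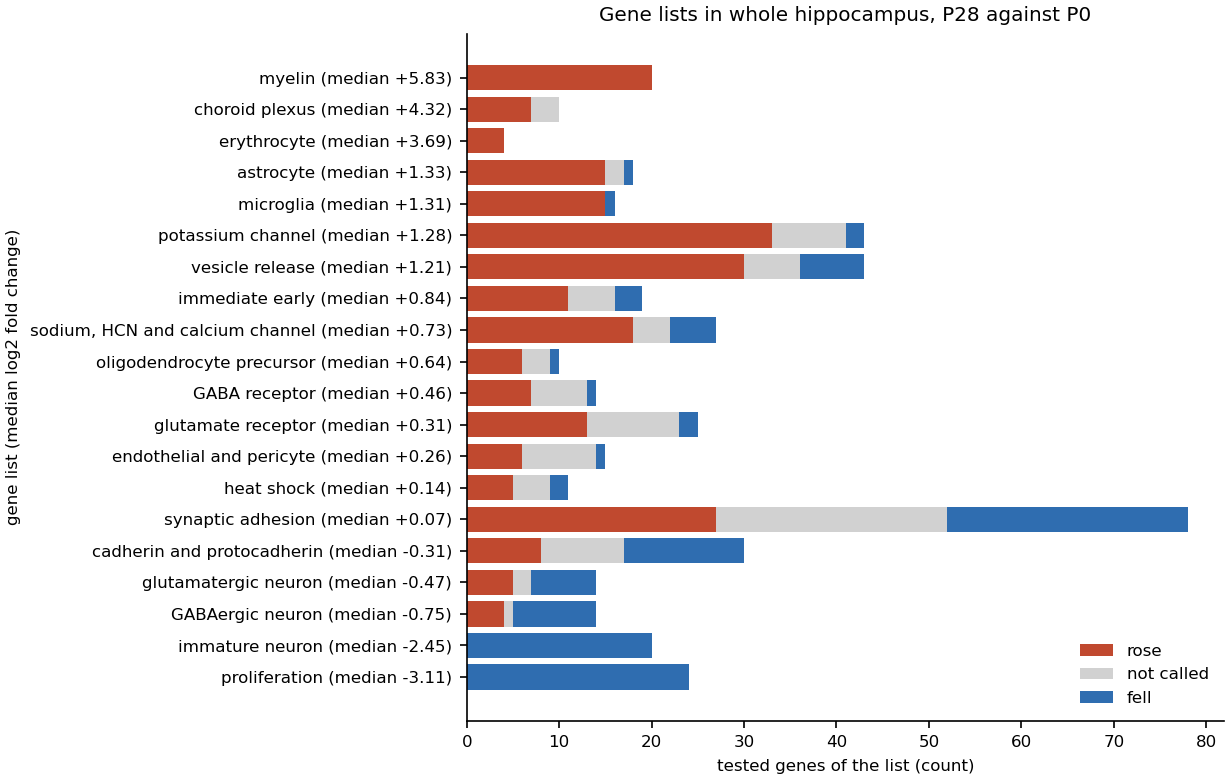
Number of tested genes (horizontal axis) in each of the 20 lists that rose, were not called or fell between P0 and P28, as stacked bars with the list's median log2 fold change beside its name (edgeR, Benjamini-Hochberg threshold 0.05, 3 libraries per age). All 20 myelin genes rose and all 20 immature-neuron genes fell, and synaptic adhesion genes split into 27, 26 and 25.

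The step from P0 to P7 asks what changes in the first postnatal week. Astrocyte genes rose as a group (17 of 18, median 0.93, adjusted p = 4.23e-18; adjusted p = 0.0108 with an estimated correlation). Aqp4 went from 106.9 to 359.7 CPM (1.78, SE 0.13, adjusted p = 5.15e-09) and S100b, a calcium-binding protein of astrocytes, rose by 2.93. Immature-neuron genes fell (14 of 20, median −0.51, adjusted p = 1.86e-12; adjusted p = 0.00687 with an estimated correlation), as did proliferation genes (21 of 24, median −0.84, adjusted p = 3.23e-08; adjusted p = 0.0182 with an estimated correlation). Among the largest decreases were Insm1 (−2.73), Nhlh2 (−2.43), Gpc2 (−2.33), Igfbpl1 (−2.26) and Mex3a (−2.08), and Sox11 and Dcx fell by 2.05 and 1.43. Sulf1, a heparan sulfatase, rose from 2.71 to 53.2 CPM.

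Oligodendrocyte precursor genes rose (7 of 10, 1 fell, median 0.98, adjusted p = 3.66e-06; adjusted p = 0.0182 with an estimated correlation), with Neu4 at 3.86 and Gpr17, a receptor of differentiating precursors, at 1.99. Of the myelin genes 13 of 20 rose (median 1.12, adjusted p = 1.31e-08; adjusted p = 0.1 with an estimated correlation), Mbp by 1.76. Endothelial and pericyte genes (12 of 15 rose, median 0.64, adjusted p = 1.11e-05; adjusted p = 0.0182 with an estimated correlation) and microglia genes (13 of 16, median 0.77, adjusted p = 7.08e-06; adjusted p = 0.0413 with an estimated correlation) rose too, among them the transporter Slco1a4 (2.51) and Tmem119 (1.73). Vesicle release genes (29 rose, 3 fell, median 0.56, adjusted p = 1.21e-10; adjusted p = 0.0108 with an estimated correlation) and potassium channel genes (25 and 1, median 0.58, adjusted p = 2.16e-09; adjusted p = 0.0124 with an estimated correlation) increased. Slc17a7 rose by 1.54, Slc12a5 by 0.96, Gad2 by 0.90 and Nrxn3 by 0.47, and Cnr1 fell by 0.69. Grin2a (0.07, adjusted p = 0.847), Slc12a2 (0.27, adjusted p = 0.148) and Nlgn1 (0.18, adjusted p = 0.194) were not called.

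Of the synaptic adhesion genes 21 rose, 7 fell and 50 were not called (median 0.17, adjusted p = 0.0734). Cntnap1 rose by 2.65 and Cbln4, a secreted partner of neurexins, by 1.74, and Cntn2 fell by 1.57. Camera called 15 lists, and 7 of these were lost with an estimated correlation. Besides myelin they were GABA receptor (9 rose, 0 fell, adjusted p = 0.00289), glutamate receptor (12 rose, 1 fell, adjusted p = 0.0103), sodium, HCN and calcium channel (13 and 5, adjusted p = 0.00105), immediate early (11 and 2, adjusted p = 0.0116), erythrocyte and choroid plexus genes (7 and 0, adjusted p = 0.0139). In that order their adjusted p values with an estimated correlation, erythrocyte genes left out, were 0.205, 0.0899, 0.0899, 0.288 and 0.436. The median of the choroid plexus list was 4.55. Ttr, a protein that the choroid plexus secretes, had 3 reads at P0 and 686 CPM at P7 (ratio 6909, counting interval 2364 to 33507, adjusted p = 0.011), a call that ended without P0 replicate 3 (adjusted p = 0.0521). Its highest P7 library had 7.34 times the CPM of its lowest. Adjusted over the list alone, 17 astrocyte genes rose and 1 fell, 1 immature-neuron gene rose and 14 fell, and 22 proliferation genes fell. Rising and falling counts so adjusted were 14 and 0 for myelin, endothelial and microglia genes, 8 and 1 for precursor, 27 and 1 for potassium channel, 30 and 4 for vesicle release, 14 and 5 for sodium, HCN and calcium channel and 11 and 3 for immediate early genes, and those of the other lists named for this step did not differ. In total 3093 genes rose and 2619 fell, and replicates did not overlap for 7319 genes (49.7%, against 10% by chance).

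Between P7 and P14 myelin genes rose and both immature-neuron and proliferation genes fell. All 20 myelin genes rose (median 4.83, adjusted p = 9.12e-117; adjusted p = 3.65e-05 with an estimated correlation). Mobp (chromosome 9, 120149707 to 120181484) went from 0.279 to 519 CPM (10.65, SE 0.22, adjusted p = 1.35e-17), and Mbp rose by 5.17. Opalin, a membrane protein of oligodendrocytes, had no read at P7 and 26.3 CPM at P14, at least 156-fold higher. All 20 immature-neuron genes fell (median −1.60, adjusted p = 8.52e-34; adjusted p = 3.65e-05 with an estimated correlation), including Dcx (−3.40, SE 0.15, adjusted p = 1.58e-12), and 23 of 24 proliferation genes fell (median −1.89, adjusted p = 2.33e-12; adjusted p = 0.0279 with an estimated correlation). St8sia2 (−4.71), Trim67 (−3.98), Tnc (−3.60) and Fabp7, a fatty acid carrier of radial glia (−3.51), had the largest decreases with Cxadr (−3.44).

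Pvalb and several transmitter and receptor genes rose in the same week. Pvalb went from 0.420 to 16.8 CPM (5.48, SE 0.37, adjusted p = 5.84e-10). Grin2a rose by 1.41 (SE 0.20, adjusted p = 1.37e-05) and Grin2c by 2.56, and Grin3a fell by 1.64. Slc12a2 rose by 0.92, Slc12a5 by 0.72, Gad1 by 0.96, Gad2 by 0.92, Slc17a7 by 1.11 and Cck by 0.86. At P14 Slc12a2 was highest in replicate 2, the library of that age with the most Ttr, but all P14 libraries lay above those of P7. Sst (0.50, adjusted p = 0.0512) was not called, except with DESeq2 (adjusted p = 0.0335), RLE scaling (0.0455), the 6 libraries of both ages alone (0.0255) and without P14 replicate 2 (0.66, adjusted p = 0.00809). Its adjusted p reached 0.207 in the other alternatives. Of the potassium channel genes 24 rose and 4 fell (median 0.55, adjusted p = 1.09e-06; adjusted p = 0.0279 with an estimated correlation), with Kcnab2 at 2.19 and Kcna1 at 1.98. Arc rose by 2.71. Of the synaptic adhesion genes 15 rose and 31 fell (median −0.24, adjusted p = 0.00633; adjusted p = 0.188 with an estimated correlation). Cntnap3 fell by 2.12, Cbln1 by 1.89 and Nrxn2 by 0.73, while Nrxn3 rose by 0.54 and Cntnap1 by 2.48.

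Of the 12 lists called at this step, 7 others were lost with an estimated correlation: astrocyte (11 rose and 2 fell, adjusted p = 2.31e-07), microglia (11 and 0, adjusted p = 2.11e-04), cadherin and protocadherin (3 and 14, adjusted p = 0.0268), erythrocyte, immediate early (10 and 3, adjusted p = 0.00913), sodium, HCN and calcium channel (13 and 4, adjusted p = 0.00633) and vesicle release genes (24 and 11, adjusted p = 0.0349). In that order their adjusted p values with an estimated correlation, erythrocyte genes left out, were 0.0669, 0.0957, 0.0751, 0.327, 0.188 and 0.327. Adjusted over the list alone, the counts of rising and falling genes that differed among these lists were 24 and 6 for potassium channels, 0 and 24 for proliferation, 11 and 3 for immediate early, 15 and 32 for synaptic adhesion and 24 and 12 for vesicle release. In all, 3197 genes rose and 3016 fell. Replicates did not overlap for 7197 genes (48.8%, against 10% by chance).

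From P14 to P21 Mbp (0.19, adjusted p = 0.25), Slc17a7 (0.08), Gad1 (0.21) and Pvalb (−0.22) were not called. Dcx and Sox11 fell further by 0.80 and 0.88. Chordc1, a co-chaperone of Hsp90 (chromosome 9, 18292125 to 18317442), fell from 71.0 to 16.8 CPM (−2.07, SE 0.14, adjusted p = 6.25e-08). Gm129, Pmaip1, a mediator of apoptosis, and Ctla2a rose by 2.03, 2.28 and 1.95. Zrsr1 and Ogdhl rose by 2.79 and 2.65. Of the immediate early genes 8 of 19 fell and none rose (median −0.53, adjusted p = 8.16e-05; adjusted p = 0.453 with an estimated correlation), Arc by 1.64 (SE 0.15, adjusted p = 7.54e-07) and Egr2 by 3.23. Immature-neuron genes fell in 10 of 20 cases (median −0.37, adjusted p = 8.77e-04; adjusted p = 0.407 with an estimated correlation) and microglia genes in 3 of 16 (median −0.17, adjusted p = 0.0341; adjusted p = 0.453 with an estimated correlation), among them Tmem119 (−1.12). Gpr17 fell by 1.34. Of the synaptic adhesion genes 5 rose, 8 fell and 65 were not called (median −0.02, adjusted p = 0.906), with Flrt3 at 0.61 and Cntnap5b at −1.52. Adjusted over the list alone, 1 immediate early gene rose and 8 fell, 1 immature-neuron gene rose and 10 fell, and the counts of the microglia and adhesion lists did not differ. With an estimated correlation 0 lists were called by camera, 1 had an unadjusted p under 0.05, and fry called 8. There were 1463 rising and 1563 falling genes. Replicates did not overlap for 5288 genes (35.9%, against 10% by chance). The count of 3026 became 1629 with libraries thinned to the smallest and 1858 without P21 replicate 2.

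From P21 to P28 Chordc1, Ctla2a and Arc changed in the direction opposite to that of the step before. Chordc1 rose from 16.8 to 52.5 CPM (1.64, SE 0.14, adjusted p = 3.49e-06), Ctla2a fell by 1.89 (SE 0.24, adjusted p = 1.7e-04) and Arc rose by 1.05 (adjusted p = 2.99e-04). Cdkn1a, an inhibitor of the cell cycle, fell from 62.6 to 19.9 CPM (−1.64, SE 0.19, adjusted p = 5.94e-05). Selplg, Ift80, Jhdm1d and Rfx3 rose by 1.33, 1.24, 1.17 and 1.17, and Pla2g3, Heyl and Agt fell by 1.74, 1.32 and 1.30. Immediate early genes rose in 3 of 19 cases (median 0.27, adjusted p = 0.00845; adjusted p = 0.41 with an estimated correlation), and 6 rose adjusted over the list alone, as did 5 glutamate receptor and 7 potassium channel genes. Glutamate receptor genes rose in 4 of 25 (median 0.10, adjusted p = 0.0367; adjusted p = 0.359 with an estimated correlation), such as the metabotropic receptor Grm7 (0.67, SE 0.09, adjusted p = 1.7e-04). Potassium channel genes (5 rose, 1 fell, median 0.13, adjusted p = 0.0439; adjusted p = 0.359 with an estimated correlation) and astrocyte genes (5 fell, median −0.17, adjusted p = 0.00826; adjusted p = 0.359 with an estimated correlation) were called as lists too. Synaptic adhesion genes gave 6 rising, 0 falling and 72 uncalled by edgeR (median 0.07, adjusted p = 0.113). Of the 26 genes fixed for naming, Grin2b alone was called (0.45, adjusted p = 0.0468), and it was no longer called without P21 replicate 1 (0.26), P21 replicate 3 (0.47), P28 replicate 2 (0.43) or P28 replicate 3 (0.36), nor with RLE scaling, no filter, thinned libraries or 6 libraries alone (adjusted p up to 0.204). The P21 libraries differed from the mean of P14 and P28 in 2589 genes, and in 1306 with thinned libraries, 1710 without P21 replicate 1 and 1310 without P21 replicate 2, a contrast chosen after the data were seen. In all, 662 of the 1154 called genes rose and the others fell. Replicates did not overlap for 4340 genes (29.5%, against 10% by chance). The count of 1154 became 406 with thinned libraries, 579 without P21 replicate 1, 481 without P21 replicate 2, 632 without P28 replicate 1, 658 without P28 replicate 2 and 513 without P28 replicate 3.

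Most single cells carried the transmitter genes of their labels. Gad1 was read in 12 of 13 PV cells and 16 of 19 CCK cells thinned to 200000 reads, against 6 of 23 CA1 pyramidal cells. Slc17a7 was read in 19 of the 23 pyramidal cells and 4 of the 19 CCK cells. Before thinning, CCK replicates 4, 8 and 19 and PV replicates 1 and 3 had no read of Gad1 or Gad2, and pyramidal replicates 1, 3, 5, 8, 16 and 24 none of Slc17a7. CCK replicate 11 held 4735 CPM of Slc17a7, more than any CA1 pyramidal cell. Pvalb was read in 8 of 14 PV cells (57.1%, exact binomial interval 28.9 to 82.3%), 2 of 19 CCK cells (10.5%, 1.30 to 33.1%) and 4 of 25 CA1 pyramidal cells (4.54 to 36.1%). The thinned cells held a median of 5372 detected genes in CCK, 4512 in PV, 2576 in CA1 pyramidal, 8963 in burst and 8944 in regular cells. The labels name no animal behind a cell, so each type is 1 sample and no test across cells was made. Ratios of cell types are log2 ratios of summed counts unless a fold is given, and their 95% intervals and floors cover counting error only. Each cell was also left out in turn, a choice made after the values were seen. Where a ratio then came over 1.5 times closer to 0 or changed direction, the value without the cell that weakened it most is given. Medians of lists that came as much closer to 0 with equal weight per cell, or in cells with or without spike-ins, have at least 1 such value beside them.

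**Figure D3:**
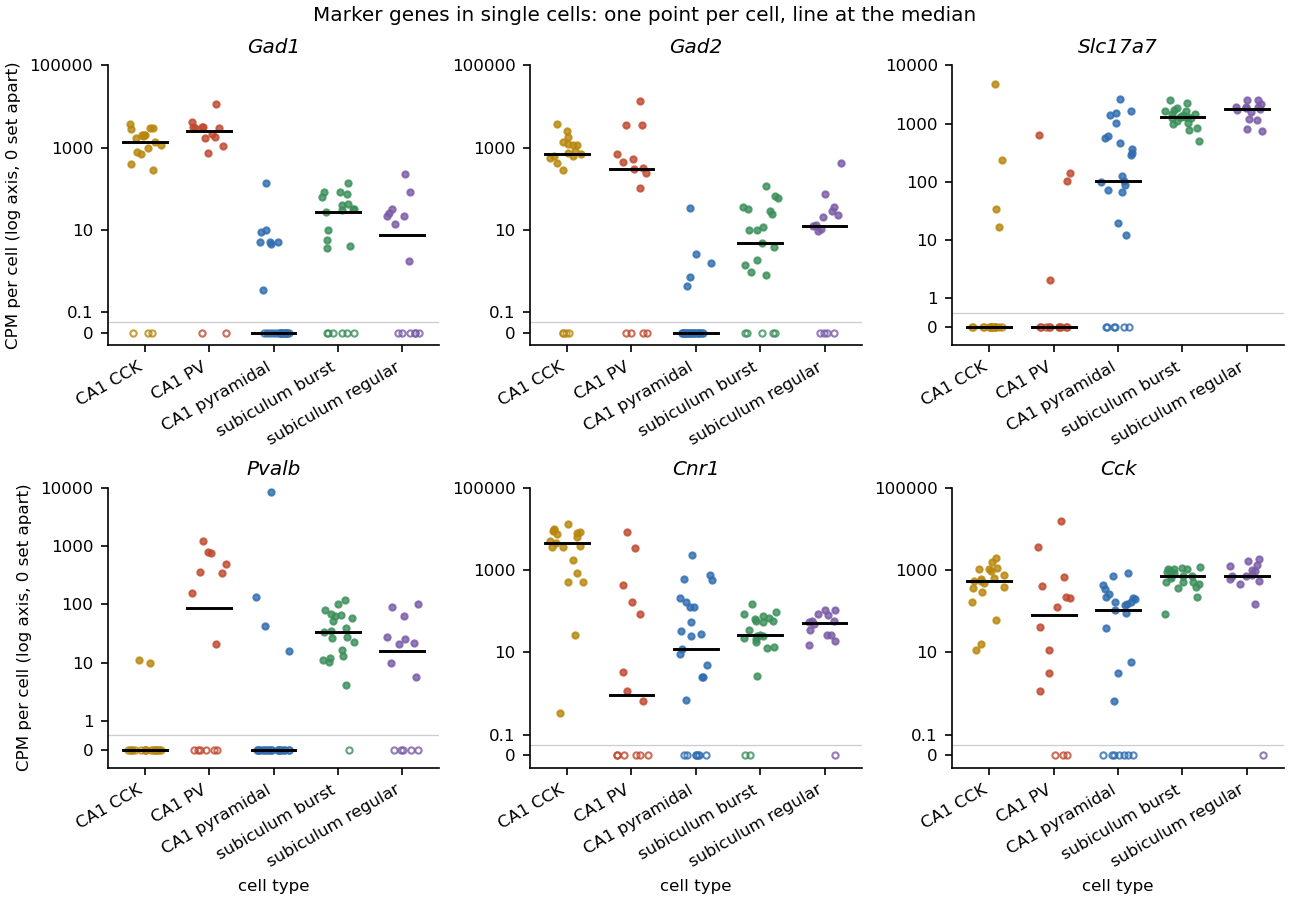
CPM (log axis) of Gad1, Gad2, Slc17a7, Pvalb, Cnr1 and Cck in each of the 93 cells, grouped by the 5 labelled types, with open circles for cells without a read and a line at the median. Pvalb was read in 8 of 14 PV cells and 2 of 19 CCK cells.

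The comparison of PV with CCK interneurons asks how inhibitory cells of one region, labelled by their firing, differ. Each type was higher in its own marker list: the median log2 ratio was 4.39 for PV genes (3.61 with equal weight), all 10 of them higher in PV cells, and −2.08 for CCK genes, 10 of 12 higher in CCK cells. Pvalb was at 338 CPM in PV and 0.648 CPM in CCK cells (log2 ratio 9.02, 8.59 to 9.49). Nxph1, a secreted ligand of neurexins (chromosome 6, 8948431 to 9249032), was at 525 and 33.8 CPM (3.96, 3.89 to 4.02). Lhx6, a transcription factor of interneurons from the medial ganglionic eminence, was at 245.1 and 0.724 CPM. Cacna2d2, a calcium channel subunit, had 105.2 CPM against 3 reads (11.18, 9.64 to 13.46). In the other direction, Cnr1 was at 1152 CPM in PV and 5439 CPM in CCK cells (−2.24, −2.26 to −2.22), and Htr3a, the serotonin-gated channel of CCK and VIP cells, at 0.459 and 214.3 CPM (−8.87, −9.74 to −8.12). PV replicates 12 and 5 held 8531 and 3413.6 CPM of Cnr1 and no read of Pvalb, and without replicate 12 Cnr1 was at 225.3 CPM in PV cells (−4.59). Syt6, a synaptotagmin (chromosome 3, 103575231 to 103645569), had no read in PV cells and 279 CPM in CCK cells, at least 2838-fold higher. Sncg, a synuclein (−6.92), Wls (−6.96), Npas1 (−5.55) and Fxyd6 (−5.48) followed. Cck itself was at 688 and 705 CPM (−0.04), and its direction depended on single cells. With equal weight per cell it was at 1.19, but at −0.50 without the highest cell of each type, which in PV cells was replicate 11 (15688 CPM). It was at 1.02 among cells without spike-ins, and at −1.19 without PV replicate 12 and 0.29 without PV replicate 4. Cacna2d2 was at 10.57 without PV replicate 12, and without CCK replicate 13 Fxyd6 was at −4.85 and Syt6 at least 1764-fold higher in CCK cells.

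The medians of receptor and channel lists were above 0 for PV against CCK cells, by amounts that depended on the setting. They were 0.96 for GABA receptors (percentile 99.95 of random lists matched on expression), 1.81 for glutamate receptors, 0.71 for potassium channels and 1.02 for sodium, HCN and calcium channels (99.99). Equal weight per cell gave 1.04, 0.75, 0.43 and 0.53 in that order, cells with spike-ins 0.73, 2.48, 0.93 and 1.31, and cells without them 1.02, 1.08, 0.90 and 0.10. Without PV replicate 4 glutamate receptors were at 1.22 and potassium channels at 0.097, and without PV replicate 2 the other channels were at 0.39. Gabra2 was higher in CCK cells (−2.43). Immediate early genes were higher in PV cells for 16 of 17 members (median 1.32, 0.65 without spike-ins). Somatostatin-cell genes had a median of 3.49 over 4 members, which became −0.34 with equal weight and −1.13 without PV replicate 2. All 16 microglia genes were lower in PV cells (median −1.77, −1.16 with equal weight and −0.92 in cells with spike-ins), among them Cx3cr1 (36.1 against 330.1 CPM). Their summed CPM in CCK cells had a median of 829.7 and a highest value of 32748, so a few cells carried much of it. Synaptic adhesion genes had a median of 0.27 (percentile 97.2, 38 of 65 higher in PV cells). That value turned to −0.069 with equal weight per cell and to −0.0042 among cells with spike-ins, which made up 9 of 14 PV and 6 of 19 CCK cells, and was 0.11 among cells without them. Without PV replicate 4 it was −0.023. Single adhesion genes differed more: Cbln4 had 85.6 CPM in PV cells and no read in CCK cells (at least 1891-fold higher), Pcdh20 had none in PV cells and 39.1 CPM in CCK cells (at least 397-fold), and Cdh6 was at 0.131 and 37.2 CPM. Nlgn1 was higher in PV cells (1.96), and Nrxn3 (−0.93) and Nlgn3 (−0.53) were higher in CCK cells. The Nlgn1 ratio rests on a few cells, since most cells of both types had no read of it. Cbln4 was at least 446-fold higher without PV replicate 4, Nlgn1 at 1.36 without PV replicate 14 and Cdh6 at −7.46 without CCK replicate 13. Of the 25 fixed genes with a value, 13 changed direction under at least 1 setting and apart from Cck are not compared.

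CCK interneurons and CA1 pyramidal cells differed in their transmitter and marker lists. All 12 GABAergic genes (median 9.34) and all 12 CCK-cell genes (7.91) were higher in the interneurons, and all 10 glutamatergic (−2.79) and all 8 CA1 pyramidal genes (−2.73) in the pyramidal cells. With equal weight per cell the last 3 were at 7.03, −1.15 and −1.11. GABAergic genes were at 7.50 in cells with spike-ins, and CA1 pyramidal genes at −2.002 in cells without. Gad2 (chromosome 2, 22622205 to 22693874) was at 1076 CPM in CCK and 0.412 CPM in pyramidal cells (11.35, 10.58 to 12.26), and Gad1 at 1933 and 8.75 CPM (7.79). Vip, a vasoactive peptide, had 646 CPM against 3 reads (12.73, 11.18 to 15.01) and Npy 103.7 CPM against 3 reads (10.09, 8.54 to 12.37). Kcnip1, a potassium channel partner, had 470.2 CPM against 3 reads (12.27, 10.72 to 14.55). Col19a1, a collagen, was at 549 and 0.159 CPM, and Synpr, a synaptic vesicle protein, at 1128 and 0.380 CPM. Cnr1 was 4.35 higher on the log2 scale and Cck 1.72. Neurod6, a transcription factor of pyramidal neurons (chromosome 6, 55677822 to 55681263), was at 0.467 CPM in CCK and 659 CPM in pyramidal cells (−10.46, −11.02 to −9.96). Sv2b, a vesicle protein (−5.05), Epha4, an ephrin receptor (−4.64), Itpka (−6.34) and Nell2 (−3.19) were lower in CCK cells too. The GABAergic median was 8.28 without CCK replicate 15, Vip at 11.80 without CCK replicate 1 and Nell2 at −2.49 without pyramidal replicate 19.

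Glutamate receptor genes were lower in CCK than pyramidal cells (median −1.96, percentile 0.01; −1.01 with equal weight). Grin2a had no read in CCK cells and 92.5 CPM in pyramidal cells, at least 2045-fold higher, and Grin2b was at 324 and 1006 CPM. Most pyramidal cells had no read of Grin2a either, while replicates 18, 19 and 21 held 364, 776 and 306 CPM. Vesicle release genes were higher in CCK cells (median 0.94, 26 of 39). Astrocyte genes (median −1.84) and Mbp (106.2 against 625 CPM) were lower in CCK cells. The summed CPM of the astrocyte list per cell, however, had a median of 1004 in CCK and 978 in pyramidal cells. Its highest values were 3718 and 22679. The synaptic adhesion median was −0.23 (percentile 7.53, 38 of 62 higher in pyramidal cells), and became 0.025 with equal weight per cell, 0.45 among cells with spike-ins and −0.39 among cells without. Cntnap4 (289.8 against 0.222 CPM), Nrxn3 (2.78) and Nlgn2, the neuroligin of inhibitory synapses (1.68), were higher in CCK cells. Mdga1 (−5.01), Nlgn1 (−2.88) and Nrxn2 (−2.10) were higher in pyramidal cells. Most cells of both types had no read of Nlgn1. Without pyramidal replicate 19 Mdga1 was at −3.69, Nrxn2 at −0.36 and Grin2a at least 1049-fold higher in pyramidal cells. Of the 26 fixed genes 10 changed direction under at least 1 setting and are not compared.

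PV interneurons against the same pyramidal cells gave a like division of transmitter genes. GABAergic genes (median 9.22, all 12) and PV-cell genes (7.58, all 10) were higher in PV cells, and glutamatergic (−3.29, 8 of 10) and CA1 pyramidal genes (−2.43, 6 of 8) lower. GABAergic genes were at 7.76 with equal weight per cell and 6.52 in cells with spike-ins, PV-cell genes at 6.11 in the latter, and glutamatergic genes at −2.48 in cells without. Gad2 was at 1669 and 0.412 CPM (11.98, 11.21 to 12.89). Nxph1 had 525 CPM against 1 read (14.02, 11.54 to 19.32). Lhx6 (at least 2577-fold), Dpp10, a potassium channel partner (at least 3093-fold), and Moxd1 (at least 2117-fold) had no read in pyramidal cells. Kcna1 was higher by 2.74. Neurod6 was at 8.196 and 659 CPM (−6.33, −6.52 to −6.15), Sv2b at 10.03 and 825 CPM, Zbtb20, a zinc finger factor of hippocampal pyramidal cells, at 4.36 and 232 CPM, and Nfia at 8.52 and 292 CPM. Pvalb was at 338 and 15.8 CPM (4.41, 4.28 to 4.54), and at −0.21 with equal weight per cell, and 1 pyramidal cell held 8360 CPM of Pvalb with no read of Gad1, Gad2 or Slc17a7. Vesicle release genes were higher in PV cells (median 1.04, 23 of 37), and astrocyte genes lower (−3.25). Summed over the astrocyte list, however, CPM per cell had a median of 820 in PV and 978 in pyramidal cells and a mean of 3474 and 3140. Single cells reached 26916 and 22679 CPM. The synaptic adhesion median was −0.43 (percentile 1.72, 36 of 66 higher in pyramidal cells), −0.18 among cells with and −0.25 among cells without spike-ins. Cntnap4 (10.27), Nlgn2 (2.15) and Nrxn3 (1.85) were higher in PV cells. Nlgn1 (−0.92) and Mdga1, without a read in PV cells (at least 761-fold), were higher in pyramidal cells. Most PV and most pyramidal cells had no read of Nlgn1. Without 1 cell Gad2 was at 11.33 (PV replicate 2), Nxph1 at least 5464-fold higher (pyramidal replicate 24), Nfia at −4.44 (pyramidal replicate 18), Zbtb20 at −5.01 (pyramidal replicate 5) and Mdga1 at least 306-fold higher in pyramidal cells (replicate 19). The medians of GABAergic genes (8.43, 11 of 12, without PV replicate 13), PV-cell genes (6.47, PV replicate 6) and astrocyte genes (−2.22, pyramidal replicate 14) came closer to 0, and that of synaptic adhesion changed direction (0.044, pyramidal replicate 19). Of the 25 fixed genes 8 changed direction under at least 1 setting and apart from Pvalb are not compared.

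Burst-firing and regular-firing cells of the subiculum were compared to ask what separates pyramidal cells of one region by firing pattern. Cdh6, a cadherin (chromosome 15, 13028701 to 13173675), was at 57.2 CPM in burst and 6.48 CPM in regular cells (3.14, 2.86 to 3.44), and read in 16 of 21 and 3 of 13 thinned cells. Cntn6, a contactin (chromosome 6, 104492790 to 104863406), was at 64.4 and 15.1 CPM (2.10, 1.90 to 2.30), read in 19 and 5 cells. Col6a1, a collagen (chromosome 10, 76708792 to 76726168), was at 0.550 and 224.6 CPM (−8.67, −9.63 to −7.87), and Serpina3n, a protease inhibitor (chromosome 12, 104406729 to 104414329), at 0.550 and 138 CPM (−7.97, −8.92 to −7.16), read in 3 burst and 10 regular cells. Fn1, fibronectin (2.20), Slc17a6, a vesicular glutamate transporter (1.05), and the factor Pou3f1 (1.65) were higher in burst cells. Neurod6 (−2.36), Nnat (251 against 948 CPM) and Dlk1 (−2.93) were higher in regular cells. Without regular replicate 4 Col6a1 was at 116.5 CPM in regular cells (−7.73) and Nnat at 596 CPM (−1.25), and without regular replicate 13 Serpina3n was at 62.1 CPM (−6.82) and Dlk1 at −2.15. Fn1 was at 1.47 without burst replicate 17. The numbers in the sample titles were compared only after the values were seen. Regular replicates 4 to 12 share a run of numbers with burst replicate 14 alone. Regular replicates 1, 2, 3 and 14, numbered among burst cells, had less Neurod6 than all of that run's regular cells but replicate 7. Against this, burst replicate 14 had no read of Serpina3n or Col6a1, and regular replicate 13, outside the run, had the most Serpina3n. Firing type and this order are partly confounded.

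Among channels, Kcnh7 (1.66), Kcna4 (1.55) and the T-type calcium channel Cacna1i (1.42) were higher in burst cells, and Kcnip2 (−2.58), Cacna1c (−1.92) and Hcn3 (−1.78) in regular cells. Syt10, a synaptotagmin, was at 11.4 and 0.545 CPM (4.38, 3.43 to 5.53). All 15 measured myelin genes were higher in burst cells (median 1.46), with Mbp at 3598 and 1573 CPM (1.19, 1.17 to 1.21). Astrocyte genes (median 0.45, 10 of 14) were higher in burst cells too. Ttr was at 352 against 163 CPM, and at 166 against 163 CPM without burst replicate 19. The median of 5 GABAergic genes was −1.55 and −0.89 with equal weight, but 0.88 without regular replicate 14, with 4 of 5 higher in burst cells. Subiculum pyramidal genes had a median of 0.75 (4 of 7 higher in burst cells), and genes of dentate and CA3 cells one of −1.61 (3 of 4 lower). The synaptic adhesion median was 0.01 (percentile 66.5, 35 of 69 higher in burst cells), and −0.078 without burst replicate 21. Cntn4 (1.36) and Nrxn3 (0.93) were higher in burst cells, and Cntnap4 (−2.23) in regular cells. Nlgn1 (0.34), Nlgn3 (0.37) and Nrxn2 (0.30) differed less. Without 1 cell Kcna4 was at 0.44 (burst replicate 7), Syt10 at 2.83 (burst replicate 21) and Cntnap4 at −0.84 (regular replicate 12).

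**Figure D4:**
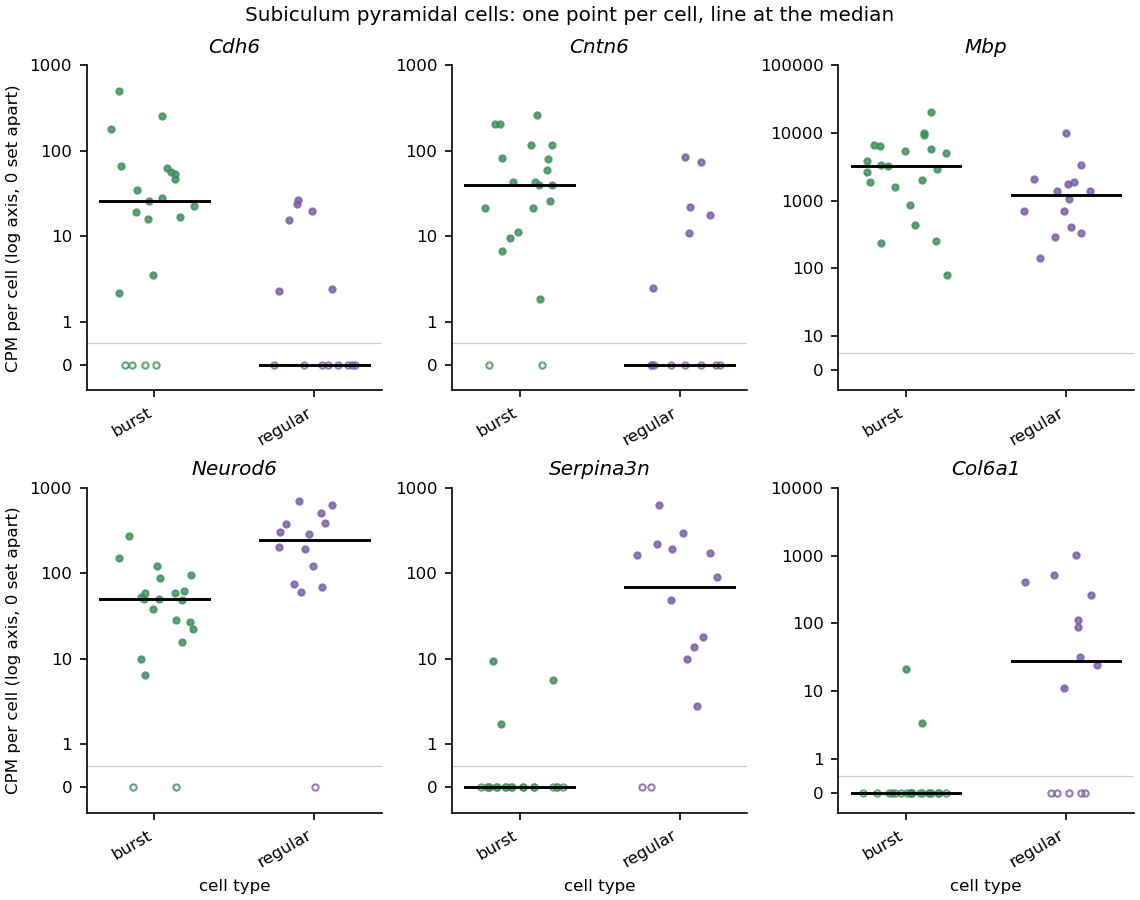
CPM (log axis) of Cdh6, Cntn6, Mbp, Neurod6, Serpina3n and Col6a1 in each of the 21 burst-firing and 14 regular-firing subiculum cells, with open circles for cells without a read and a line at the median. Pooled Cdh6 was 57.2 CPM in burst and 6.48 CPM in regular cells, and pooled Serpina3n 0.550 and 138 CPM.

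CA1 and subiculum pyramidal cells were prepared with kit versions 3 and 4, so region and kit cannot be told apart in their contrast. Subiculum genes were lower in CA1 cells (median −7.15, 6 of 7; −4.88 with equal weight). Slc17a6 was at 0.349 CPM in CA1 and 49.4 CPM in subiculum cells, Cdh13, a cadherin, at 0.159 and 227.4 CPM (−10.49, −12.11 to −9.26), and Nov at 212.3 and 1159.7 CPM. Mest, an imprinted gene (chromosome 6, 30723547 to 30748465), had no read in CA1 cells and 556 CPM in the subiculum, at least 5849.8-fold higher, and was read in 33 of 34 thinned subiculum cells. Grm2, a metabotropic glutamate receptor (at least 1816-fold), and Tbr1, a cortical transcription factor (at least 254-fold), had no read in CA1 cells either. In CA1 cells Fibcd1, a marker of CA1, was at 415 against 22.4 CPM (4.21, 4.11 to 4.32), Neurod6 at 659 against 153 CPM and Man1a at 168 against 39.8 CPM. CA1 pyramidal genes as a list had a median of 0.39 (4 of 8), −0.01 with equal weight and −0.43 without pyramidal replicate 9 of CA1. Grin2b (2.04), Gabra5 (2.10) and Kcnq3 (125.7 against 4.10 CPM) were higher in CA1 cells, and Slc17a7 (379 against 1513 CPM) and Cck (−1.86) in the subiculum. Microglia genes (median 2.03, 13 of 16 higher) and myelin genes (−3.74, 12 of 13 lower; −2.37 with equal weight) also differed, the former by 0.38 without CA1 replicate 5. Without CA1 replicate 18 Kcnq3 was at 4.12 and Ncam2 at 2.31. The synaptic adhesion median was −0.12 (percentile 43.6, 37 of 67 higher in the subiculum), and 0.027 after TMM scaling, which shifted all ratios by 0.15. Ncam2 (3.74) and Nlgn1 (2.65-fold) were higher in the summed counts of CA1 cells. Nlgn2 (−1.67) and Lrrtm3, without a read in CA1 cells (at least 953-fold), were higher in the subiculum. The Nlgn1 ratio rests on a few CA1 cells, such as replicates 11 and 22 with 705 and 626 CPM. Most CA1 pyramidal cells had no read of Nlgn1, whereas all subiculum cells but regular replicate 5 held reads. Of the 26 fixed genes 4 changed direction under at least 1 setting and are not compared.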

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

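Of the tests in this part, those of depth as the whole cause, of carry-over and of single high cells in the subiculum, the contrast of P21 with its neighbours, and all splits of the libraries were chosen only after the result was seen.

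Spike-in sequences, which no comparison uses, were read above 0.1% of all reads in 6 CCK, 9 PV and 9 CA1 pyramidal cells. Their lowest share was 1.66% and their highest 57.6%, against at most 0.0167% in the other 34 CA1 cells and 0.000287% in tissue and subiculum libraries.

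Many genes of the P21 libraries stood apart from both P14 and P28: 2589 differed from the mean of those ages, and 1306 with thinned libraries, 1710 without P21 replicate 1 and 1310 without P21 replicate 2. Called against each age, 329 genes were higher and 500 lower than at both. Across all genes P21 correlated with P28 at 0.979, no less than P14 did (0.977), and with P14 at 0.968. A lower temperature during dissection stays open. Of 9 heat shock factor targets edgeR called 0 lower (1 at an unadjusted p under 0.05) and 1 higher, which was set beforehand to argue against it. That bound was wrong to leave out Rbm3, a cold-induced gene written down with those 9 before its value was seen, which was higher (0.80, adjusted p = 2.28e-06). The fixed heat shock list, left out as already seen, went both ways. Of the 11 genes of that list 2 were lower and 1 higher than at the mean of both ages (median −0.12, adjusted p = 0.612), and from P14 to P21 4 fell and 1 rose (median −0.20, adjusted p = 0.223). Chordc1, a co-chaperone of Hsp90, was lower (−1.85, adjusted p = 8.74e-08) and Cirbp, another cold-induced gene, higher (1.29, adjusted p = 2.51e-09), but these 2 prompted the explanation and do not support it. Time of day may have differed, but of 7 clock genes in phase with Per1 2 were higher (Tef 0.30, Nr1d1 0.35) and 2 lower (Per2 −0.34, Per3 −0.59), so it stays open. Sequencing depth as the whole cause is argued against. Mean depth at P21 (10.7, in units of 1e+06 reads) lay between those at P14 and P28 (9.89 and 11.1), and with log2 depth as a covariate, itself called in 2892 genes, 99.7% of the calls were made again. With thinned libraries 46.0% were made again in the same direction and 94.8% kept their sign. The calls lost there had a median log2 change of 0.41 before and 0.36 after thinning, with a median SE of 0.11 and 0.16, so their loss does not show depth as the cause. The age itself is an untested biological explanation.

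Choroid plexus genes were uneven between libraries of one age, with Ttr differing 69.1-fold between P21 libraries and 19.7-fold between P28 libraries. Choroid plexus tissue carried along in some dissections is a candidate explanation: in 4 of 5 ages the library with the most Ttr had the highest sum of the other 9 choroid genes. The exception was P0, where Ttr was near its floor. Depth as the whole cause is argued against. The library with the most Ttr was the deepest in 3 of 5 ages but the shallowest in 2, and after removal of the depth trend the highest library of an age still had 5.36, 11.2, 29.3 and 9.46 times the Ttr of the lowest at P7, P14, P21 and P28. The libraries nearest in depth, 1.26-, 1.01-, 1.10- and 1.06-fold apart at these ages, differed 3.96-, 1.08-, 30.9- and 1.20-fold in Ttr. So at P14 and P28 only the shallowest library stood out, with the most Ttr at P14 and the least at P28. Depth took up 14.5% of the variance of log2 Ttr within the later 4 ages (5.69 to 46.2% without 1 library, highest without P14 replicate 2), and a smaller part for it stays open. No biological explanation was tested.

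Myelin genes were higher in burst than regular cells, 4824 against 2046 summed CPM. RNA of oligodendrocytes in the samples is a candidate explanation. The excess followed the tissue level at P21 across the 20 myelin genes (Spearman rho 0.789), which are not independent replicates. Other sources of tissue RNA could give the same relation, so it does not tell oligodendrocytes from carry-over. Carry-over of tissue RNA stays open. The astrocyte excess was 0.170 of the share that the myelin excess makes up of tissue and the endothelial one −0.056, which went against it. Those of microglia and choroid plexus genes were 0.313 and 2.47. The choroid value depended on the highest burst cell, with 4943 summed CPM against a median of 71.8. The value of oligodendrocyte precursor genes was −0.228, but the median log2 ratio of their list changed from −0.38 to 1.58 without regular replicate 11. Burst replicates 3, 4, 8, 11, 13, 15, 16 and 19, with the most Mbp, all held reads of Sst, Npy and Gad1. Of those with the least, replicates 2 and 14 held none and replicate 9 at most 4.02 CPM. Replicate 7, with 1867 CPM of Mbp, held the most Sst (174 CPM). A few cells with very high counts are argued against, since 76.2% of burst cells (16 of 21, exact interval 52.8 to 91.8%) were above the median of regular cells. A difference between the firing types themselves is an untested biological explanation.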

How the results depend on the processing

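The estimated correlation for the 4 steps, cells with or without spike-ins, cells under 1000 detected genes left out, the P21 libraries or each cell left out, depth as a covariate and the contrast of P21 with its neighbours were chosen only after the results were seen. In tissue 90 of the alternative counts of genes and lists stayed within 1.5 times their value and 18 did not. Thinning every library to the smallest gave 1629 genes for P21 against P14, 406 for P28 against P21 and 1306 for P21 against the mean of P14 and P28. Thinning leaves fewer reads, and depth so limits the 2 last steps. Depth as a covariate gave 3922 genes for P21 against the mean. Leaving out each library in turn gave 8671 to 9208 genes for P28 against P0, 4387 to 5320 for P7 against P0, 5212 to 6173 for P14 against P7, 10555 to 11411 for all ages and 11 to 12 lists for P28 against P0. It gave 1858 to 2779 for P21 against P14 (1858 without P21 replicate 2), 481 to 869 for P28 against P21 (579 without P21 replicate 1, 481 without P21 replicate 2, and 632, 658 and 513 without P28 replicates 1, 2 and 3), and 1310 to 2626 for P21 against the mean (1710 without P21 replicate 1, 1310 without P21 replicate 2). Fewer libraries were fitted there. Without the P21 libraries 9403, 5626 and 6105 genes were called in the first 3 contrasts and 10311 among the remaining ages. A replicate block gave 9351, 5480, 6067, 2820 and 940 genes in the order of the contrasts, 11082 for all ages and 12 lists. Replicate numbers do not pair the libraries, since only 3 of 15 correlated best with their own number and residuals of same-numbered pairs correlated at −0.27 to 0.16. With an estimated correlation camera called 6 lists for P28 against P0 (fry 19), 8 for P7 against P0, 4 for P14 against P7, and 0 for P21 against P14 (1 at an unadjusted p under 0.05, fry 8) and for P28 against P21 (1 and 6). Fry does not compare a list with other genes. Values of named tissue genes kept their side of the threshold in 6144 alternatives, lost a call in 300 and gained one in 60. A further 95 changed the sign of an uncalled value, and 0 reversed a called one under edgeR or DESeq2.

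The synaptic adhesion medians of cells moved beyond counting error in 15 alternatives, reversed in 5 and stayed within it in 11, and the cause was not tested. Equal weight per cell gave −0.069 for PV against CCK (reversed), 0.025 for CCK against CA1 pyramidal (reversed) and −0.36 for CA1 against subiculum pyramidal cells. TMM scaling gave −0.29 for CCK and −0.52 for PV against CA1 pyramidal cells, and 0.027 (reversed) for CA1 against subiculum cells. These are shifts that all genes of a comparison share, so they do not bear on adhesion genes relative to others. They were 0.0008, −0.06, −0.09, 0.03 and 0.15 for PV against CCK, CCK and PV against CA1 pyramidal, burst against regular and CA1 against subiculum cells. A minimum of 1 CPM gave 0.19 for PV against CCK, −0.18 and −0.39 for CCK and PV against CA1 pyramidal, and −0.19 for CA1 against subiculum cells. Leaving out cells under 1000 detected genes gave 0.35, −0.27, −0.36 and −0.083 in that order. Cells with spike-ins gave −0.0042 (reversed) for PV against CCK, 0.45 (reversed) for CCK and −0.18 for PV against CA1 pyramidal cells, and cells without gave 0.11, −0.39 and −0.25. The median for burst against regular cells was within counting error of 0.01 under these alternatives. Leaving out each cell in turn gave −0.023 to 0.51 for PV against CCK, −0.32 to −0.11 for CCK and −0.62 to 0.044 for PV against CA1 pyramidal, −0.078 to 0.10 for burst against regular and −0.27 to −0.036 for CA1 against subiculum cells. Of the genes compared in the report, 17 of 20, 17 of 23, 13 of 18, 13 of 26 and 6 of 20 then moved by over 1.5 times in that order, and Cck in PV against CCK cells alone changed direction (−1.19 to 0.29). Of all named genes in cells, 36 for PV against CCK, 21 for CCK and 31 for PV against CA1 pyramidal, 8 for burst against regular and 13 for CA1 against subiculum cells changed direction under at least 1 setting. Those compared in the report stayed within counting error in 87 of the other alternatives, reversed in 3 and moved beyond it in the rest. The reversed were Cck in PV against CCK cells (1.19 with equal weight, 1.02 without spike-ins) and Pvalb in PV against CA1 pyramidal cells (−0.21 with equal weight).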

Other observations

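The values in this part were set side by side, and the splits of the libraries tested, only after the results were seen.

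Parvalbumin reads were not limited to fast-spiking cells. Pvalb was read in 29 of 35 subiculum pyramidal cells, 20 of 21 burst and 9 of 14 regular, at pooled levels of 38.4 and 22.8 CPM. Most cells with Pvalb also held reads of Sst, but burst replicates 2, 12, 18 and 21 and regular replicate 5 did not. Burst replicate 14 and regular replicates 1, 4, 6, 7 and 12 lacked Pvalb. Of these, none held Npy, and regular replicate 1 alone held Sst. RNA of other cells in the samples therefore stays open as a source of the Pvalb reads. Genes of other cell types were present in the pyramidal cells of both regions. Microglial P2ry12 was at 746 CPM in CA1 and 13.6 CPM in subiculum pyramidal cells, and Fcrls at 503 and 12.4 CPM, while without CA1 pyramidal replicate 5 the CA1 levels were 285 and 34.8 CPM. Glutamatergic cells of the subiculum also held more transcripts of immediate early genes (median −1.23 for CA1 over subiculum, 15 of 18 lower in CA1) and of vesicle release genes (−0.80, 29 of 38 lower in CA1), with region and kit version confounded.

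Single genes were out of step with age in tissue. Cirbp, a cold-inducible RNA-binding protein, averaged 114.8 CPM at P7, 64.8 at P14, 204.2 at P21 and 107.05 at P28. Per1, a clock gene, averaged 11.7 CPM at P14, 45.1 at P21 and 19.4 at P28, and these genes were singled out after their values were seen. Cry1, a clock gene of the opposite phase, was 0.63 higher at P21 than at the mean of P14 and P28 (adjusted p = 3.14e-04). The other genes of that phase were not called by edgeR: Arntl (0.12, adjusted p = 0.409), Npas2 (0.34, adjusted p = 0.311) and Clock (−0.35, adjusted p = 0.0614). Of 19 immediate early genes 6 were lower at P21 than at that mean (median −0.39, adjusted p = 4.16e-04; adjusted p = 0.738 with an estimated correlation).

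Exchanging libraries between ages tested whether chance can be excluded. For genes differing among the 5 ages, the rank of the real split argues against a chance assignment of the age labels. Of 60 splits 1, the real one, gave as many as 11266 genes, and the highest other gave 45. The other splits mixed ages within their groups, so 45 is not a count of chance alone and only the rank is used. For contrasts of 3 against 3 libraries the 10 splits are too few for a share under 0.05. Every split but the real one also mixed libraries of both ages within its groups. The age difference then widened the spread within groups and in part remained between them. Counts of the other splits are therefore not those of chance alone. The real and the highest other counts of genes were 9465 and 0 for P28 against P0, 5712 and 0 for P7 against P0, 6213 and 0 for P14 against P7, 3026 and 1 for P21 against P14, and 1154 and 6 for P28 against P21, each with 1 split as large. For lists they were 12 and 11, 15 and 12, 12 and 11, 3 and 7, and 4 and 7 in the same order, with 1, 1, 1, 6 and 3 of 10 splits as large.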
